A study of Homo sapiens with 12 samples.

How the data were processed

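The samples were primary human CD4 T cells, the helper T cells that carry the CD4 coreceptor. Per the labels' protocols, naive and memory cells were enriched with magnetic beads by negative selection, in which unwanted cells are bound and removed. They were collected at 0 h (rest) or after 48 h of culture with beads carrying antibodies against CD3 and CD28, which engage the T cell receptor complex and its costimulatory receptor. There were 12 libraries in 4 groups of 3. Per the same protocols, total RNA was purified with TRIzol and converted to cDNA with an Ovation RNA-seq kit. The cDNA was digested with S1 nuclease, ligated to indexed adapters, amplified by PCR and sequenced on an Illumina GAIIx. Whether the kit kept strand information is not given in the sources used here, so reads of overlapping antisense genes were taken as inseparable.

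The authors deposited 1 RPKM value per gene symbol and library (reads scaled by transcript length and by the mapped reads of the library), with 21174 gene rows in each library. Per the submitters' processing notes, CASAVA 1.5, TopHat 1.4 and Cufflinks 2.0.2 were used with genome build hg18; their roles, their order and the denominator of the RPKM values are not given in the sources used here. Genes were named by the deposited symbols, and no coordinates are printed because the reference at hand was of another build. XIST, TSIX and Y-linked genes, 61 rows in all, were left out of every step, which left 21113. DNA methylation data, to which the title of the series refers, were not used here.

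Read counts were not used, so total depth is unknown and no counting interval is given. Relative depth was read from genes with low values, whose commonest ratio between 2 libraries is taken as that of genes with the same small number of reads. It rested on 239 to 674 genes per library and ran from 0.193 to 1.24 of the depth of 1 resting naive library, a ratio of 6.42. The second lowest was 0.619. RPKM totals per library ran from 88161 to 202105, and no added RNA standard was used here, so a change of the whole library and a change of its scale are not separable. From 6927 to 8609 genes per library had an RPKM of at least 1. A gene listed at 0 was below detection in that library.

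The following were fixed before the data were examined: the groups, the tests, the gene lists, the rule for naming genes and the alternative settings other than those named below as chosen after seeing the data. Values were analysed as log2(RPKM + 1) on the deposited scale. This scale understates the changes of low genes. Genes with an RPKM of at least 1 in at least 3 libraries were tested (9063 genes). limma 3.58.1 in R 4.3.3 fitted the 4 group means over all 12 libraries, with a variance prior that followed mean expression, and gave 5 two-sided comparisons: memory against naive at rest and at 48 h, 48 h against rest in each subset, and the difference of the 48 h responses. P-values were adjusted over all genes tested within a comparison by the Benjamini-Hochberg method, and adjusted p under 0.05 was called. Errors beside log2 fold changes are standard errors; errors beside RPKM values are standard deviations. The labels do not say that the 3 libraries of a group came from separate donors, so the p-values measure the spread between these libraries. Values were joined and plotted with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

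The named genes of a comparison are the 6 largest rises and 6 largest falls among called genes with a mean RPKM of at least 5 in the higher group and no overlap between the libraries compared. The overlap condition was not used for the difference of responses. From each of 17 pathway lists, up to 4 called members with a mean RPKM of at least 2 and up to 2 members not called with the highest mean were eligible as examples. A fixed set of 9 identity genes was CD3E, CD4, CCR7, SELL, FAS, S100A4, CD69, IL2RA and MKI67. The pathway lists and 11 cell type marker lists held 458 entries, of which 457 were found. Lists were tested with camera from limma with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 17 pathway lists of a comparison, and again with an estimated correlation. camera asks whether a list stood apart from the other genes. Overlaps of calls were tested with Fisher's exact test. Lists contained families with near-identical copies, such as histones, whose reads the authors' counting could have split between copies.

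Log2 values were simulated with the real means and residual spreads of 9063 genes and with noise independent between genes. The 200 genes changed were drawn from those with a mean log2 value above 2. For memory against naive cells at rest, the test with 12 libraries called 14.9% of genes changed by 1 log2 unit, 58.2% by 2 and 80.3% by 3. For the difference of responses these shares were 0%, 31.3% and 65.2%. They do not cover lower genes or libraries that depart in many genes at once.

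The profiles of 2 libraries did not match their group labels. Labels were kept as given, no library was moved to another group, and the main results use all 12 libraries. Each count of changed genes was repeated without these 2 libraries, also with the same median in every library, quantile normalization or a replicate block, and the counts of gene lists and of shared genes without these 2 libraries alone. These alternatives were chosen after seeing the data. Because those libraries were left out on the basis of their values, the remaining ones look more alike than randomly chosen libraries would, and p-values from the 10 libraries are too small to that extent. Their groups then held 2 libraries each.

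A number that opens each label is shared by 1 library of each group, and the labels do not say what it marks. The correlations across genes between the deviations of same-numbered libraries from their group means ran from -0.431 to 0.312, and 12 of 18 pairs exceeded 0.1. All 3 pairs of both subset comparisons did (0.304, 0.238 and 0.189 at rest; 0.271, 0.312 and 0.11 at 48 h), so the number was taken to pair the libraries there. The main results come from the fit without a block, as fixed before, and the value with the block is printed beside results of these comparisons whose call it changed. It was not so treated for the activation comparisons, where pairs fell to -0.041 in naive cells and 0.038 in memory cells. The other pairs there were at 0.197 and 0.226 in naive and 0.161 and 0.247 in memory cells, so pairing is not excluded. Named activation genes are not marked for the block. The pairing comes from these correlations alone. The alternatives were other pseudocounts, filters, scalings and variance models, library weights, a replicate block, and fits that left out each library or the 4 libraries sharing a number.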

Results

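RNA sequencing measured gene expression in naive and memory human helper T cells, resting or activated for 48 h through CD3 and CD28. Naive T cells have not yet met their antigen and memory T cells have. The series concerns how memory is recorded in CD4 T cells, and the comparisons ask which transcripts separate the subsets before activation, which separate them after it, and how far their responses differ. Each of the 4 groups held 3 libraries. RPKM totals ran from 88161 to 202105 per library, and the deepest library was 6.42 times as deep as the shallowest.

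All 11 T cell markers had a mean RPKM of at least 1 in every group, and the medians of their group means lay between 12.2 and 19.1. CD3E, a chain of the T cell receptor complex, was at 35.2 ± 9.8 (SD, n = 3) in resting naive cells and 32.7 ± 2.0 in memory cells at 48 h. Markers of other lymphocytes were low: the highest group mean among them was 0.265 for CD8 T cells (CD8B), 0.403 for B cells (BANK1) and 1.27 for natural killer cells (KLRF1). The highest erythroid value was 1.96 (HBB in resting naive cells). The monocyte transcript LYZ averaged 1.48 in resting naive, 14.0 in naive 48 h, 24.0 in resting memory and 0.057 in memory 48 h libraries. Its 3 values in the naive 48 h group were 0, 0 and 42.0. LYZ was the highest monocyte marker in naive 48 h libraries only. S100A8 was highest in resting naive (4.919) and resting memory libraries (44.44), and CD68 in memory 48 h libraries (22.97). The platelet transcript PPBP averaged 40.8 in libraries labelled naive 48 h, where its 3 values were 0.163, 0.324 and 121.8. In resting naive libraries its values were 3.17, 5.83 and 45.4, and the libraries at 45.4 and 121.8 share a label number. Of the dendritic cell markers, FCER1A was highest, at 2.18 in libraries labelled resting memory. Among markers of regulatory T cells, which restrain other T cells, CTLA4 was highest in every group and FOXP3 reached 3.05 in memory 48 h libraries.

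Activation markers showed 2 libraries that did not match their group labels, 1 labelled naive 48 h and 1 labelled resting memory. IL2RA, the high-affinity interleukin-2 receptor chain that activated T cells display, was at 2.54, 82.7 and 83.0 RPKM in the naive 48 h group and at 3.86, 4.07 and 100.4 in the resting memory group. MKI67, a proliferation marker, was at 2.83, 106.9 and 109.8 in the former and 2.39, 2.67 and 44.4 in the latter. The first principal component held 53.8% of the variance and the third 9.9%, and together they set the 2 libraries apart from the rest of their labelled groups. The second held 14.3% and is not drawn. On it the 4 libraries sharing 1 label number, these 2 among them, scored 17.57 to 40.78, and the 8 others 11.15 or lower. With these 2 left out of the groups, each of the 10 others correlated best with the rest of its own group, while with all 12 kept 6 of the 12 did. Values without these 2 libraries are given below as an alternative chosen after seeing the data, and its p-values are too small because the libraries were left out by their values.

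**Figure D1:**
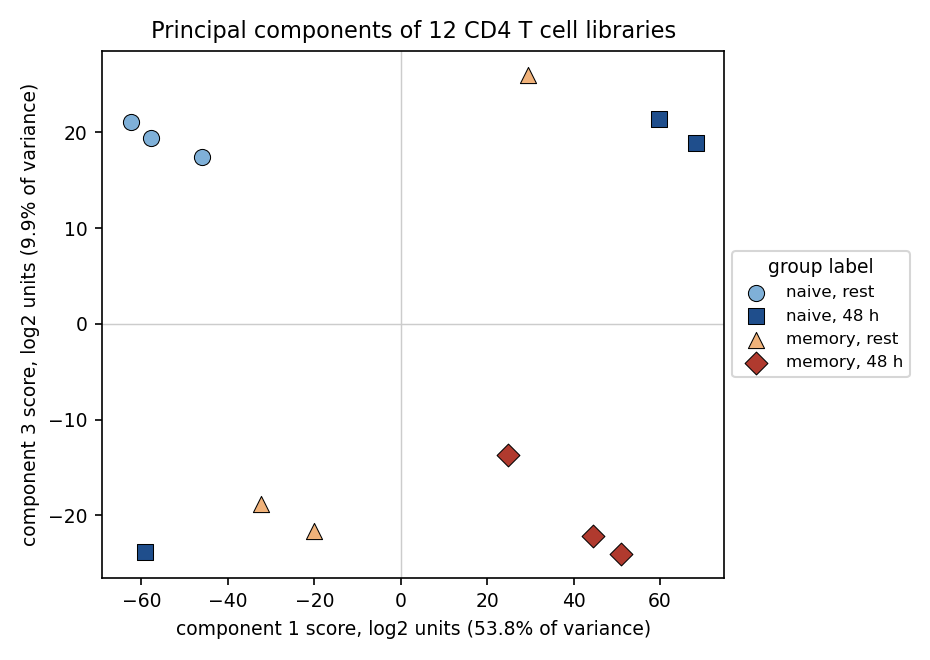
Scores of the 12 libraries on the first (horizontal) and the third (vertical) principal components of log2(RPKM + 1) values, in log2 units, with 1 point per library and colour and shape for its group label. Resting and 48 h libraries separate along the horizontal axis and subsets along the vertical axis, except for 1 library labelled naive 48 h and 1 labelled resting memory.

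At rest, memory cells differed from naive cells by 15 genes with higher and 6 with lower expression. CCR4, a chemokine receptor of skin-homing and type 2 helper cells, was at 26 ± 17.1 RPKM (SD, n = 3) in libraries labelled memory and 0.626 ± 0.437 in naive libraries, a log2 fold change of 3.78 ± 0.64 (limma, adjusted p = 0.0427). The phospholipid-binding protein gene ANXA5 was at 50.6 ± 12.2 in memory and 4.92 ± 0.33 in naive libraries, and the death receptor gene FAS at 18.9 ± 3.1 and 2.11 ± 1.38 (adjusted p = 0.00208 and 0.00937). FAM129A, the kinase gene TBK1 and the inhibitory receptor gene CTLA4 were also higher, by 3.30, 2.39 and 2.08 on the log2 scale. RFTN1, a lipid raft protein gene, was at 104.1 ± 16.6 in naive and 30.5 ± 7.3 in memory libraries, and AK5 and PCSK5 were lower in memory cells by log2 changes of -1.79 and -1.90. With the replicate number as a block the 12 libraries gave 8 higher and 2 lower genes, among them 9 of these 21; CCR4, FAM129A, TBK1, AK5 and PCSK5 were then not called (adjusted p = 0.0927, 0.0599, 0.0599, 0.0504 and 0.0504).

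Of 17 gene lists, 8 stood apart from the other genes at rest and 2 did with an estimated correlation. CCR4 and FAS were the 2 of 25 memory surface and migration genes called higher, and 6 adjusted over the list alone. The list's median log2 change was 1.63 (camera adjusted p = 2.04e-07, and adjusted p = 0.408 with an estimated correlation). None of 20 naive T cell and lymph node homing genes was called by limma over all genes, and 5 were lower adjusted over the list alone; this list stood below the other genes (median -0.77, adjusted p = 7.46e-15, and 0.0241 with an estimated correlation). CCR7 and SELL, receptors for entry into lymph nodes, were at 25.4 and 68.3 RPKM in naive and 11 and 45.0 in memory libraries (adjusted p = 0.538 and 0.387). Lineage transcription factors stood above the other genes (median 0.998, adjusted p = 0.00012, and 0.0241 with an estimated correlation, which was 0.0597 with the block), with none of 18 called singly and 4 adjusted over the list alone. The activation receptor list was above the other genes as well (adjusted p = 0.00109, and adjusted p = 0.753 with an estimated correlation), with CTLA4 as its single called member and 2 adjusted over the list alone. The lists of endoplasmic reticulum stress, cell cycle and histone genes were above and that of quiescence genes below the other genes, and none of these 4 calls held with an estimated correlation (adjusted p = 0.753, 0.882, 0.882 and 0.753). Interferon-stimulated genes, which respond to antiviral cytokines, did not stand apart (median 0.01, adjusted p = 0.123), and their median was -0.36 with the same median in every library.

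With the 2 libraries left out, 647 genes were higher and 66 lower in resting memory cells, including all 21 calls made with 12 libraries. The higher genes then were led by KLRB1, a lectin-like receptor of interleukin-17-producing and innate-like T cells, at 118.5 RPKM in 2 memory libraries and 1.82 in 3 naive libraries, and included the transcription factor gene PRDM1 (log2 fold change 4.24 ± 0.46, adjusted p = 0.00122) and S100A4 (4.03 ± 0.90, adjusted p = 0.0257). Of 25 memory surface and migration genes 18 were higher, of 8 cytotoxic molecule genes 4, among them the granzyme genes GZMA and GZMK, and of 18 lineage transcription factor genes 9. With an estimated correlation adjusted p was 0.0617, 0.468 and 0.225 for these lists. Of the naive and lymph node homing genes 7 were lower, among them LRRN3, PECAM1 and the repressor gene BACH2 (adjusted p = 0.0775 with an estimated correlation). The quiescence list had a median of 0.47, against -0.29 with 12 libraries, the cell cycle list 0.75 against 1.44, and the activation receptor list 0.57 against 1.07, with its camera call lost (adjusted p = 0.0971). S100A8 and LYZ, transcripts of monocytes and neutrophils, were among the genes with the largest differences (4.56 ± 0.89 and 4.26 ± 0.52), while CD14 was listed at 0 in all libraries. FOS and DUSP1, immediate early genes of the handling stress list, were at 60.4 and 69.3 RPKM in the 2 memory libraries and 11.5 and 14.8 in naive libraries. The same median in every library turned the split of calls at rest from 15 higher and 6 lower to 6 and 16, and quantile normalization to 16 and 35.

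At 48 h, activated memory cells expressed cytokine and chemokine genes that activated naive cells expressed at a low level or not detectably. There were 80 genes higher and 5 lower in memory cells. IFNG, the type 1 helper cytokine interferon gamma, was at 72.2 ± 27.2 RPKM (SD, n = 3) in memory and 2.53 ± 1.74 in naive libraries (log2 fold change 4.46 ± 0.49, limma adjusted p = 0.00125). The interleukin-17 genes IL17F and IL17A, products of the Th17 lineage, were at 26.1 ± 13.8 and 11.8 ± 6.8 in memory libraries (adjusted p = 0.000554 and 0.000502). In naive libraries IL17F was at 0.262 ± 0.454 and IL17A was listed at 0. IL9 was at 21.1 ± 9.9 in memory libraries and listed at 0 in the 3 naive libraries (adjusted p = 0.000306). The transcription regulator genes HOPX and MAF were higher by 3.90 ± 0.35 and 3.48 ± 0.48. Of the 85 genes 55 were also called with the replicate block; of the genes named here for 48 h, TNFRSF9, IL1R1 and MAP4K4 were not (adjusted p = 0.0929, 0.0732 and 0.056).

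Of 17 lists, 12 stood apart from the other genes at 48 h and 2 did with an estimated correlation. Of 21 cytokine and chemokine genes 12 were higher in memory cells and 17 adjusted over the list alone, with a median log2 change of 2.60 (camera adjusted p = 6.22e-35, and 0.00199 with an estimated correlation). They included the chemokine genes CCL3 and CCL4, at 57.9 ± 42.9 and 94.8 ± 40.3 RPKM in memory libraries against 0.713 ± 0.815 and 2.59 ± 1.66; reads that these share with near-identical copies are uncertain. Of 18 lineage transcription factor genes 2 were called, HOPX and MAF, and 5 adjusted over the list alone, and the list held with an estimated correlation (adjusted p = 0.00345, and 0.0995 without the 2 libraries, where the call was lost). Among activation receptors, CTLA4 was at 199.6 ± 42.6 in memory and 30.7 ± 6.9 in naive libraries, and TNFRSF9 was higher by 2.87 ± 0.57; these were the 2 of 20 called, with 4 adjusted over the list alone (adjusted p = 0.276 with an estimated correlation). Of 24 cytokine signalling genes 3 were higher, the interleukin-1 receptor genes IL1R1 and IL1R2 and the interleukin-23 receptor gene IL23R, and 3 were adjusted over the list alone (adjusted p = 0.276 with an estimated correlation). None of 8 cytotoxic molecule genes was called by limma and 4 were higher adjusted over the list alone (adjusted p = 0.0001, and adjusted p = 0.224 with an estimated correlation). The 5 lower genes were OXNAD1, LEF1, TRIM22, MAP4K4 and AK5. LEF1, a transcription factor of naive T cells, was at 15.7 ± 2.5 in memory and 66.3 ± 25.0 in naive libraries and was the single called member of 20 naive and lymph node homing genes (list adjusted p = 0.000184, and adjusted p = 0.274 with an estimated correlation). Cholesterol and fatty acid synthesis genes stood above the other genes (median 0.56, adjusted p = 4.51e-05, and adjusted p = 0.355 with an estimated correlation), with none of 17 called singly or adjusted over the list alone.

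**Figure D2:**
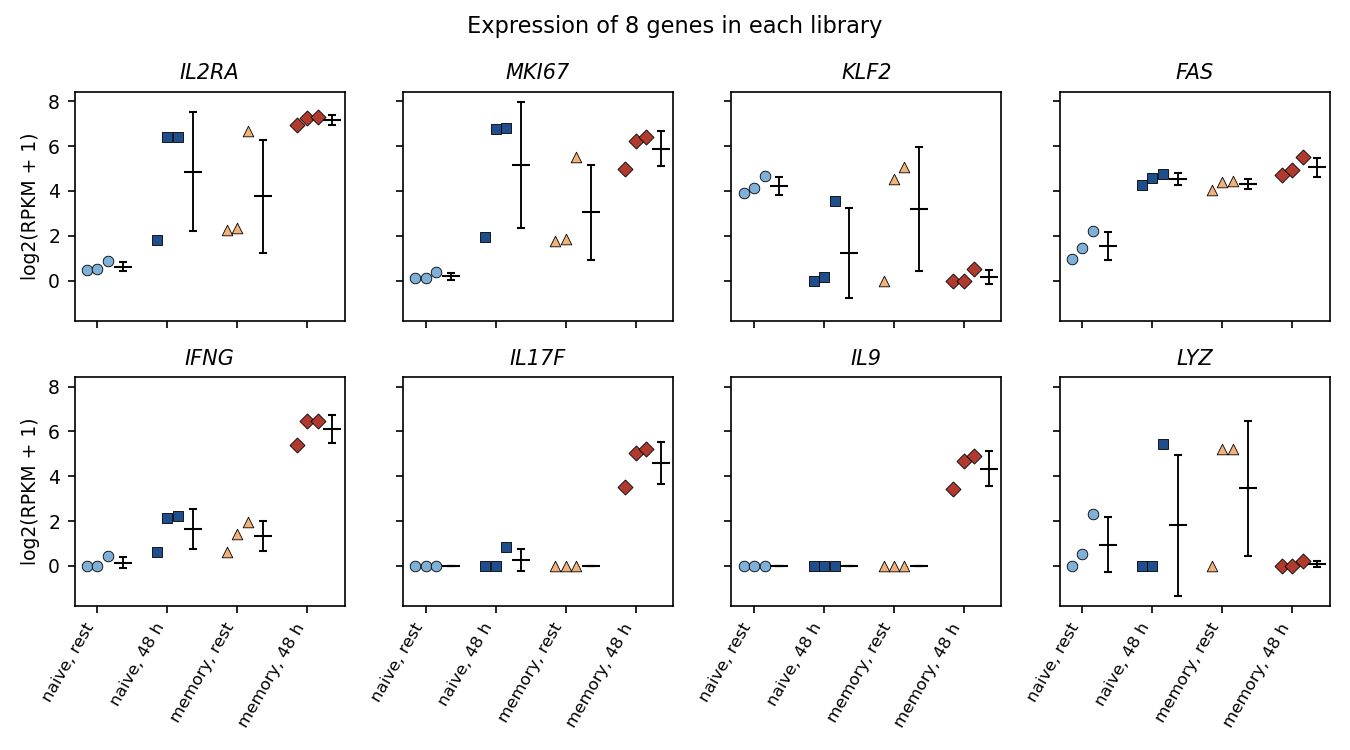
Expression of 8 genes as log2(RPKM + 1) in the 12 libraries by group label, with 1 point per library in order of value and a bar for the mean and SD of the 3 libraries. IFNG, IL17F and IL9 were highest in the 3 memory 48 h libraries, while IL2RA, MKI67, KLF2 and LYZ show 1 library of the naive 48 h and 1 of the resting memory group far from the rest of its group.

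Without the 2 libraries, 254 genes were higher and 518 lower in memory cells at 48 h, including all 85 calls made with 12 libraries. The lower genes were led by PRG4, which encodes lubricin, at 6.37 RPKM in memory and 102 in 2 naive libraries, followed by the small GTPase gene RAB13 and the transcription factor gene IRF8 (log2 fold changes -3.89, -3.25 and -2.66). Of 31 cell cycle genes 13 were lower and of 19 replication-dependent histone genes 10, and adjusted p was 0.28 and 0.272 with an estimated correlation. Reads shared between the near-identical histone copies are uncertain. The cytokine list kept its side, with 13 of 21 genes higher, 1 lower and adjusted p = 0.0331 with an estimated correlation. With the same median in every library these 10 libraries gave 484 higher and 250 lower genes, so the balance of the directions at 48 h turned with the scale.

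In naive cells, 48 h of activation raised 50 genes and lowered 12. With the replicate block 34 rose and 8 fell, and the genes named here are not marked for it. BHLHE40, a transcription factor gene induced in activated T cells, went from 0.418 ± 0.124 to 49.5 ± 38.8 RPKM (SD, n = 3), a log2 fold change of 4.54 ± 0.81 (limma, adjusted p = 0.0359). PMAIP1, which encodes the apoptosis protein NOXA, and WEE1, a kinase gene of the cell cycle, rose by 3.41 ± 0.62 and 3.14 ± 0.61. FAS rose from 2.11 ± 1.38 to 22.3 ± 4.0 (adjusted p = 0.00727), and HERPUD1, a gene of the endoplasmic reticulum stress response, rose by 2.73 ± 0.48. LRRN3, a gene characteristic of naive T cells, fell by 2.05 on the log2 scale, and RFTN1 fell from 104.1 ± 16.6 to 31.6 ± 5.5. AK5, PCSK5, ZNF238 and NAA16 also fell. YWHAH, the interleukin-2 receptor chain gene IL2RB, the interferon-stimulated gene GBP5 and the interleukin-18 receptor gene IL18R1 rose.

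No more than 2 members of any list were called in naive cells with all 12 libraries. Of 17 lists, 9 stood apart from the other genes and none did with an estimated correlation. Adjusted over the list alone, 30 of 31 cell cycle genes and 12 of 20 glycolysis genes rose, and the camera calls of these lists (adjusted p = 1.35e-08 and 0.000351) were lost with an estimated correlation (adjusted p = 0.652 for both). MKI67 had a log2 difference of 4.96 ± 1.26 and IL2RA of 4.25 ± 1.28, neither called over all genes (adjusted p = 0.084 and 0.107), and the library that did not match its label was low for both. Without the 2 libraries, 3917 genes rose and 537 fell, including all 62 calls made with 12. TOP2A, MKI67 and TYMS, genes of DNA replication and division, then rose by 6.79 ± 0.30, 6.57 ± 0.36 and 6.44 ± 0.44, and IRF4, a transcription factor gene of T cell activation, went from 2.87 to 260 RPKM. All 31 cell cycle, 19 histone and 19 serine, one-carbon and nucleotide synthesis genes rose, as did 19 of 20 activation receptor genes, 18 of 20 glycolysis genes, 14 of 17 cholesterol and fatty acid synthesis genes, and 13 of 18 ribosome biogenesis genes. With an estimated correlation the adjusted p of these 7 lists lay between 0.203 and 0.668. GAPDH and LDHA of glycolysis rose by 5.03 ± 0.48 and 4.03 ± 0.38. KLF2, TXNIP and ITGA6 fell, and 11 of 18 quiescence genes fell with KLF2 and TXNIP among them (adjusted p = 0.203 with an estimated correlation). FOS and DUSP1 fell as well (from 11.5 and 14.8 to 0.246 and 0.525 RPKM), and of 8 cytotoxic molecule genes 2 rose and 2 fell.

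Over all genes tested, the median log2 change in naive cells was 0.39 with 12 libraries and 0.61 without 2. With the same median in every library, 52 genes rose and 78 fell in the 12 libraries, and 1724 rose and 2076 fell in the 10. Relative to the median of all genes, the cell cycle list lay 2.29 and the histone list 1.92 higher with 12 libraries, and 3.32 and 3.22 higher without 2. Of the DNA methylation machinery, 8 of 14 genes rose and 1 fell in the 10 libraries, among them the maintenance methyltransferase gene DNMT1 (from 7.72 to 32.7 RPKM, adjusted p = 0.000415) and the dioxygenase gene TET2 (from 3.58 to 13.1). This list did not stand apart from the other genes (adjusted p = 0.6), and none of its members was called by limma with 12 libraries, over all genes or over the list alone. Ribosome biogenesis genes did not stand apart with 12 libraries (adjusted p = 0.448).

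**Figure D3:**
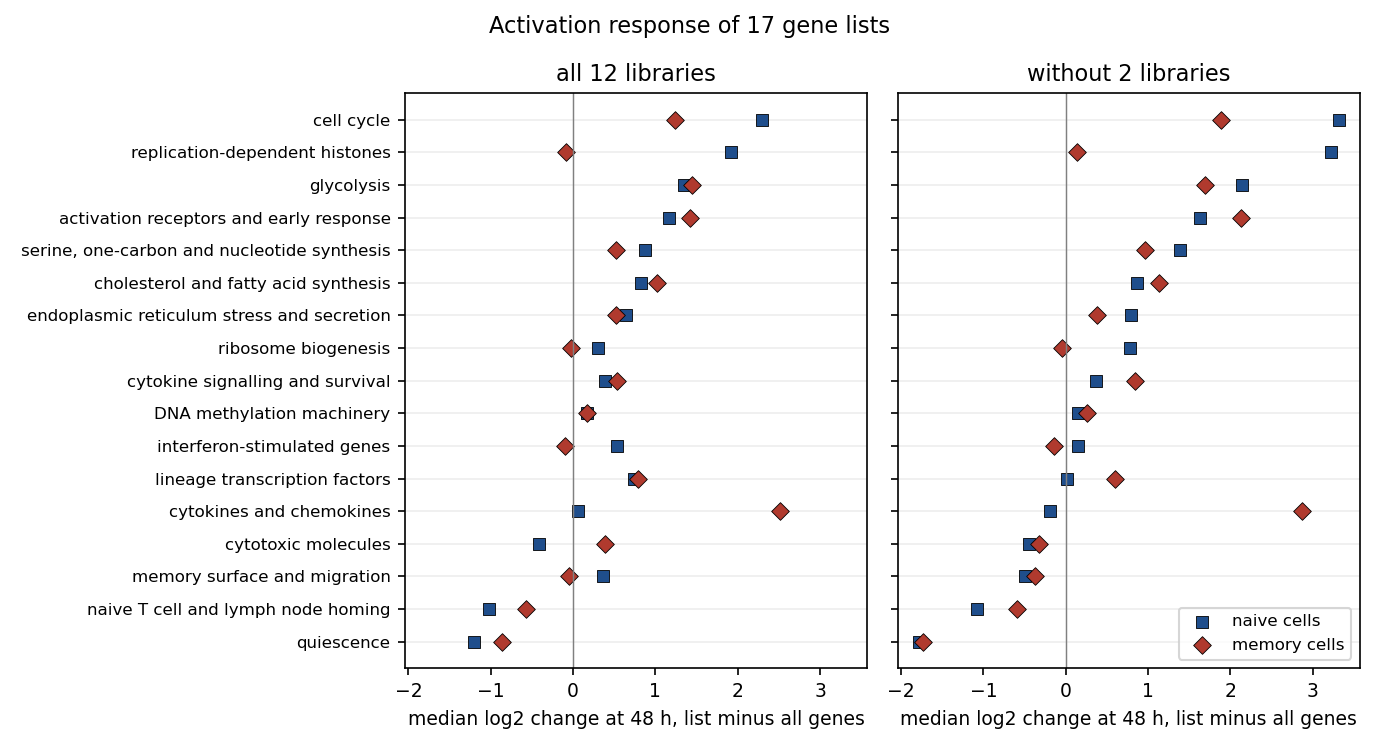
Median log2 change at 48 h of 17 gene lists relative to the median of all genes tested, in naive (squares) and memory cells (diamonds), with all 12 libraries (left) and without the 2 libraries that did not match their labels (right). Cytokines and chemokines lay 2.51 above all genes in memory cells and 0.06 above in naive cells with 12 libraries, and quiescence genes lay below all genes in both subsets.

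In memory cells, 48 h of activation raised 98 genes and lowered 21. With the replicate block 66 rose and 10 fell, and the genes named here are not marked for it. GZMB, the cytotoxic protease granzyme B, rose from 1.49 ± 2.35 to 90.5 ± 45.6 RPKM (SD, n = 3), a log2 fold change of 5.46 ± 1.06 (limma, adjusted p = 0.0331), and the DNA sensor gene AIM2 from 9.66 ± 11.3 to 267.2 ± 45.2 (adjusted p = 0.0173). IFNG rose by 4.78 ± 0.49 and the chemokine gene CCL20 by 3.71 ± 0.33. IL17F and IL9 were listed at 0 in the 3 libraries labelled resting memory and were at 26.1 ± 13.8 and 21.1 ± 9.9 at 48 h (adjusted p = 0.000363 and 0.000153). OXNAD1 fell from 49.6 ± 15.2 to 8.80 ± 2.27, and SESN3, RASGRF2, PRKACB, NRIP1 and the calcium-dependent kinase gene CAMK4 also fell. LEF1 fell from 49.0 ± 8.6 to 15.7 ± 2.5.

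Of 17 lists, 11 stood apart from the other genes and 2 did with an estimated correlation. Of 21 cytokine and chemokine genes 12 rose in memory cells and 17 adjusted over the list alone (median 2.53, camera adjusted p = 1.97e-27, and 0.00465 with an estimated correlation). Among activation receptors 4 of 20 rose, the inhibitory or costimulatory receptor genes CTLA4, LAG3, HAVCR2 and TNFRSF9 (11 rose and 1 fell adjusted over the list alone; list adjusted p = 1.45e-08, and adjusted p = 0.25 with an estimated correlation). MAF and HOPX rose among 18 lineage transcription factor genes, and 3 adjusted over the list alone (adjusted p = 0.0243 with an estimated correlation). Neither the cytokine nor the transcription factor list held with an estimated correlation when the 2 libraries were left out (adjusted p = 0.136 and 0.382). INSIG1, a regulator of sterol synthesis, was the single called gene of 17 in cholesterol and fatty acid synthesis, with 7 adjusted over the list alone (list adjusted p = 2.07e-08, and adjusted p = 0.25 with an estimated correlation). Without the 2 libraries 1357 genes rose and 876 fell, including all 119 calls made with 12, and 25 of 31 cell cycle genes rose but 2 of 19 histone genes (adjusted p = 0.222 and 0.932 with an estimated correlation). IL2RA and MKI67 then rose by 4.86 ± 0.20 and 4.06 ± 0.36, and 14 of 18 quiescence genes fell (adjusted p = 0.136 with an estimated correlation). KLRB1 fell from 118.5 to 7.07 RPKM. The falls were led by S100A8, FOS, DUSP1 and LYZ, at 66.7, 60.4, 69.3 and 36 RPKM in the 2 resting libraries and 0.214, 0.235, 0.816 and 0.057 at 48 h. With the same median in every library the 10 libraries gave 1237 rises and 1339 falls.

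The difference of the 48 h responses was called for 10 genes with a larger rise or smaller fall in memory cells and 1, the small nucleolar RNA gene SNORA13, with a larger fall. IL9, IL17F, IL17A and CCL20 responded more in memory cells (limma, adjusted p = 0.0109, 0.0254, 0.0246 and 0.0365). With the replicate block 1 gene was called, IL9 (adjusted p = 0.0489), while IL17F, IL17A and CCL20 were not (adjusted p = 0.0567, 0.0567 and 0.0606), nor were the other genes named in this paragraph. At 48 h they were at 21.1, 26.1, 11.8 and 15.0 RPKM in memory libraries, and in naive libraries IL9 and IL17A were listed at 0 and IL17F and CCL20 were at 0.262 and 0.589. CTSL1, a cathepsin protease gene, went from 1.91 ± 1.36 to 12 ± 2.15 RPKM in memory cells and from 3.17 ± 0.60 to 0.331 ± 0.378 in naive cells, a difference of 3.92 ± 0.48 (adjusted p = 0.0215). EMP1, a membrane protein gene, was at 5.04 ± 0.98 in memory and 0.202 ± 0.175 in naive 48 h libraries (adjusted p = 0.0312). Of 21 cytokine and chemokine genes 7 were called and 12 adjusted over the list alone, CCL3 and CCL4 among them, and the list stood above the other genes also with an estimated correlation (adjusted p = 0.00154), though not without the 2 libraries (adjusted p = 0.0694). The lists of cell cycle and histone genes stood below the other genes (medians -1.37 and -2.41, adjusted p = 0.0321 and 8.08e-05, the former 0.0953 with the block) with no member called over all genes or adjusted over the list alone, and adjusted p = 0.868 and 0.715 with an estimated correlation.

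Without the 2 libraries, the difference of responses, memory minus naive, was positive for 68 genes and negative for 888, a smaller rise or a larger fall in memory cells. Of 31 cell cycle genes 20 and of 19 histone genes 15 responded less in memory cells (adjusted p = 0.583 for both with an estimated correlation), with TOP2A at -2.93 ± 0.42 and MKI67 at -2.51 ± 0.51. RAB13 and MND1 rose less in memory cells, and IRF8 was called as a rise only in naive cells (log2 differences -4.30, -3.86 and -3.83). The noncoding RNA genes RPPH1 and RMRP, with log2 differences of -4.96 and -4.28, were highest in resting memory cells. The median log2 difference of all genes was -0.57, and with the same median in every library the split became 188 positive and 167 negative.

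**Figure D4:**
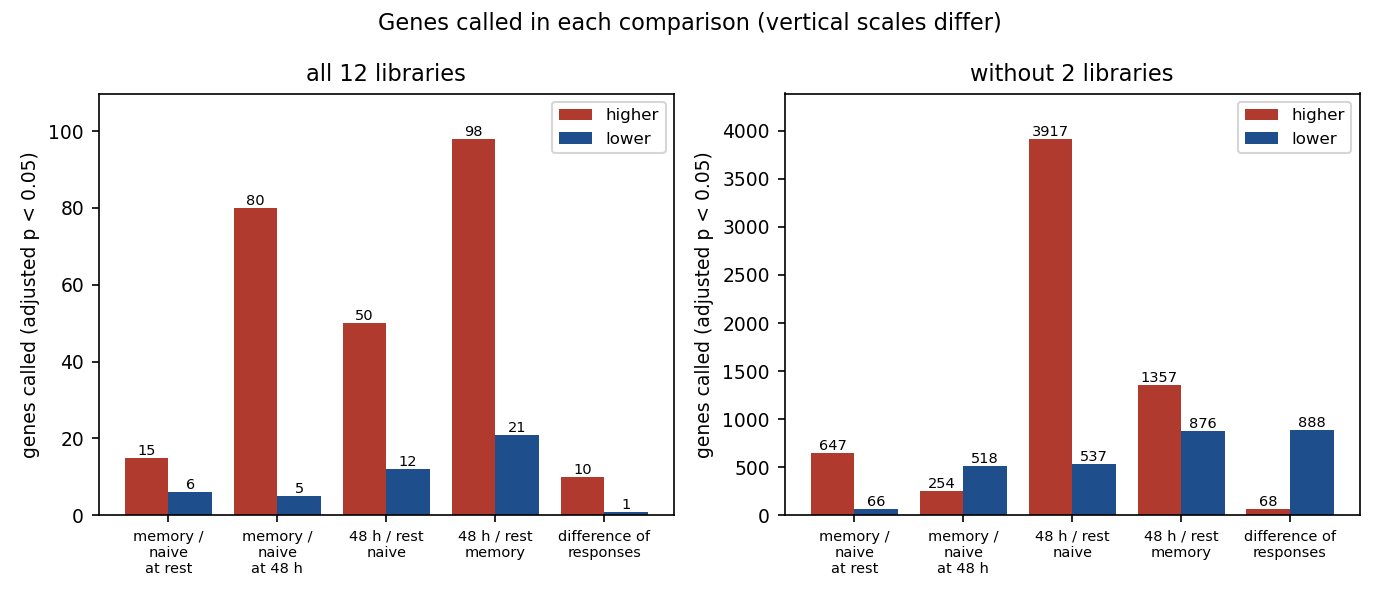
Number of genes called higher (red) and lower (blue) by limma at adjusted p under 0.05 in the 5 comparisons, with all 12 libraries (left) and without the 2 libraries that did not match their labels (right), on different vertical scales. Activation in naive cells gave 50 rises and 12 falls with 12 libraries and 3917 and 537 without 2.

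The activation responses of the subsets shared 5 rises, against 0.541 for independent lists of 50 and 98 genes (Fisher's exact test, p = 0.000192), and 1 fall against 0.028 (p = 0.0275). The shared rises were CTLA4, IL2RB, FRMD4B, APOBEC3C and RNF19A and the shared fall AK5, named after their values were seen. Without the 2 libraries they shared 1164 rises against 586 and 329 falls against 51.9. The subset comparisons at rest and at 48 h shared 2 higher genes against 0.132 (Fisher's exact p = 0.0075) and 1 lower gene against 0.0033, which were CTLA4 and RNF19A, and AK5. Of these, RNF19A and AK5 were not called at rest with the block (adjusted p = 0.0599 and 0.0504). The group means compared in each pair had no library in common, but the spread of each gene came from the same fit of all groups. The expected numbers and Fisher's exact p-values take the calls of the 2 comparisons as independent, which they then are not. Genes are not independent replicates, and these p-values treat them as such.

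The 4 libraries that share 1 of the numbers in the labels had a lower share of ribosomal protein genes, 5.57% to 7.85% of the RPKM total against 8.51% to 18.6% in the 8 others. They comprised 1 library of each group and included both libraries that did not match their labels, so the counts below are not separate from those without 2 libraries. Among the 8 others, memory cells at rest had 515 higher and 55 lower genes and at 48 h 223 and 254. Activation then gave 3682 rises and 563 falls in naive cells and 1565 and 814 in memory cells, and the difference of responses was called for 45 genes upward and 310 downward. The set of 4 held 1 library per group, too few for a test of its own.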

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

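The tests of the libraries that did not match their labels, of scale, of scaling and transcription in resting memory libraries, and of more RNA per cell were chosen only after the result was seen.

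For 11 genes the 48 h response differed between the subsets in a test of the difference itself. The fitted differences, memory minus naive on the log2(RPKM + 1) scale, were 4.88 for CCL3, 4.34 for IL9, 4.31 for IL17F, 3.92 for CTSL1, 3.72 for CCL4, 3.48 for IL17A, 3.12 for CCL20, 2.21 for EMP1, 2.05 for IL13, 1.95 for EPAS1 and -1.81 for SNORA13. For genes listed at 0 in a group these values depend on the pseudocount and are no bounds. SNORA13, a small nucleolar RNA gene, was at 2.57 RPKM in libraries labelled resting memory and listed at 0 in the 3 other groups. All 11 were also called without the 2 libraries, but the count was 1 with the replicate block, 0 by limma with pseudocount 0.1 (664 had an unadjusted p under 0.05 in the fit of 12) and 0 to 355 when libraries were left out. Of 100 random regroupings of the 12 libraries, the real one included, 3 called as many genes and the highest other 268. Those regroupings ignored the numbers of the labels; of 100 that kept 1 library of each number in every group, drawn only after the result was seen, 5 called as many and the highest other 4349. Regrouping also moves the activation and subset effects between groups, so neither share tests the difference of responses alone. Chance is thus not excluded. Both highest counts were many times the 11 of the real groups. They can come from the activation or subset effect of the real groups, so they do not show a structure outside the groups. Which regroupings gave them was not examined.

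Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. The real split called 21 genes for memory against naive cells at rest and the highest other 7. At 48 h the real split called 85 and the highest other 1. For activation the real split called 62 in naive cells and 119 in memory cells, and the highest others 6 and 2. Every other split mixes the 2 real groups, so an effect between them widens the spread within the mixed groups. Lower counts were therefore largely fixed in advance and are no test of the calls.

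The profiles of 2 libraries did not match their labels, 1 labelled naive 48 h and 1 resting memory. Low sequencing depth as the only cause is argued against: on 404 genes with a mean RPKM of at least 50 in the 10 others, where few reads add little noise, 0 of the 2 were closest to their labelled group, by 0.327 and 0.529 in correlation, although 1 of the 2 was the shallowest of the 12 libraries (relative depth 0.193, next lowest 0.619). An exchange between the 2 groups stays open as a candidate explanation, since on all genes tested 2 of 2 were closest to the other's group, but the smallest gap was 0.011 and on the 404 genes 0 of 2 were. Weak activation in one library and activation before the beads in the other was tested too. Of the genes that separate the subsets, 62.9% lay nearer the other subset in 1 library and 67.6% in the other, past a bound of 60. On the 404 genes both were closest to a group of their labelled subset, with a smallest gap of 0.013, and 9 of the 10 others to their own group. That result can lean toward the labelled subset, because those groups still held a library with the label number that the 2 libraries share. The groups of the exchange held none, so the 404 genes do not count against an exchange. On the third principal component the library labelled naive 48 h scored -23.86 and that labelled resting memory 26.01. Each lay on the side of the other subset. These scores and the shares past 60 argue against a kept profile of the labelled subset, but each rests on 1 library. Exchange and weak or early activation are both left open. The test of depth on the 404 genes replaced one on all genes that could not have come out otherwise. All was found and tested on the same data, and no label was changed.

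Without the 2 libraries, 10 of 14 tested myeloid genes were called higher in resting memory than in resting naive libraries, by a median of 2.56. LYZ and S100A8 were among the 10. The 14 are those of 19 monocyte and dendritic cell markers and 16 further genes that passed the filter of genes tested. FCER1A passed only through the 2 resting memory libraries (3.83 and 2.73 RPKM) and the mismatched naive 48 h library (2.34). The 14 thus depend partly on the group where they were high, and 10 of 14 is no share of all these genes. Equal medians took the median of all genes from 0.30 to -0.02. The median of these 10 was then 2.24 (median standard error 0.30) and 7 stayed called. MNDA (1.79 ± 0.43 to 1.46 ± 0.41), FGL2 (1.53 ± 0.34 to 1.20 ± 0.30) and IFI30 (1.22 ± 0.30 to 0.90 ± 0.30) lost their calls with that shift. The 10 were picked as called higher in the same fit, so a median above a bound of 0.5 was fixed in advance. The values show only that the shift of all genes was smaller than these differences. Earlier versions of the test gave 0.10 over all 19 listed genes, most near 0, and 1.05 over 8 of them. Myeloid cells carried through the negative selection may contribute: over 16 further myeloid and antigen presentation genes the median was 0.51, just past the bound of 0.5 written before, but the lower quartile was 0.11, a condition added afterwards, so this is left open. HLA-DRA was at 0.464 RPKM in resting naive and 32.8 in resting memory libraries and CD74 at 6.91 and 39.0, genes that activated T cells also express, the dendritic cell markers FCER1A, CD1C and FLT3 were at 3.28, 1.19 and 1.14 in resting memory and 0.197, 0.063 and 0 in resting naive libraries, and CPVL was 2.77 higher, while CST3 was at 0.439, S100A9 at 1.68 beside S100A8 at 66.7, and CD14 was listed at 0. Transcription of these genes by the memory T cells, with LYZ 4.26 higher, cannot be told apart from this in mixed RNA.

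Activation of naive cells without the 2 libraries gave 3917 rises and 537 falls. With the same median in every library 45.4% of the calls were rises, but equal medians bring about such a balance whatever the cause. The median change of all genes was 0.61. More RNA per activated cell would not by itself raise it in values scaled by the mapped reads of each library, and the denominator used is not given. Without an outside standard these values therefore cannot show a change in RNA per cell. The scale of the deposited values stays open.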

How the results depend on the processing

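The fits without 2 libraries, alone or with another scaling or a block, were chosen only after the data were seen. They left out libraries by their values, so their counts are too high to an unknown extent. An exchange of the 2 libraries, left open above, would in turn tend to lower the counts with 12 libraries. Of 76 named called results none reversed, and 76 were called in the 4 fits without 2 libraries and with library weights. With the replicate block 32 were no longer called (in the subset comparisons those named beside their values, and no other named call changed there), with only the libraries of the groups compared 47, and when 4 libraries sharing a number were left out 0 to 76. The counts of genes depended on the processing in each comparison, and where no cause follows from the setting (fewer libraries, fewer genes), the cause was not tested.

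Memory against naive cells at rest gave 21 genes. The count was 51 with pseudocount 0.1, 51 with quantile normalization, 10 with the replicate block, 5 with only the libraries of the groups compared and 2463 with library weights. It was 713 without 2 libraries, 432 with the same median added, 493 with quantile normalization added and 585 with the block added. Leaving out each library or each number gave 0 to 570.

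Memory against naive cells at 48 h gave 85 genes. The count was 25 with pseudocount 0.1, 27 with an RPKM of at least 5 in at least 3 libraries, 40 with values rescaled to the same sum, 0 by limma with only the libraries of the groups compared (745 had an unadjusted p under 0.05 with all 12) and 2120 with library weights. Without 2 libraries it was 772, and 734, 570 and 553 with the same median, quantile normalization and the block added. Leaving out gave 0 to 477.

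Activation in naive cells gave 62 genes. The count was 204 with pseudocount 0.1, 29 with no filter on low values, 121 rescaled to the same sum, 130 with the same median, 145 with quantile normalization, 0 by limma with only the libraries compared (2349 unadjusted with all 12) and 5301 with library weights. Without 2 libraries it was 4454, and 3800, 3562 and 4314 with the same additions in that order. Leaving out gave 0 to 4245.

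Activation in memory cells gave 119 genes. The count was 36 with pseudocount 0.1, 41 with an RPKM of at least 5, 37 rescaled to the same sum, 76 with the replicate block, 79 with only the libraries compared and 3898 with library weights. Without 2 libraries it was 2233, and 2576, 2554 and 2398 with the same additions. Leaving out gave 0 to 2379.

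The difference of responses gave 11 genes. The count by limma was 0 with pseudocount 0.1, 4 with 0.5, 22 with no filter, 0 with an RPKM of at least 5 (664 unadjusted in the fit of 12), 2 rescaled to the same sum, 21 with the same median, 1 with the replicate block, 7 with a variance prior without trend and 2848 with library weights. Without 2 libraries it was 956, and 355, 245 and 276 with the same additions. Leaving out gave 0 to 355.

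Gene lists that stood apart numbered 8, 12, 9, 11 and 8 of 17 in the 5 comparisons, and with an estimated correlation between genes 2, 2, 0, 2 and 1. For the difference of responses, leaving out each number gave 5 to 10. Rises shared by the activation comparisons numbered 5, and 10 with the same median, 14 with quantile normalization, 3 with the replicate block and 1164 without 2 libraries; shared falls numbered 1, and 3, 5 and 329 with the same median, quantile normalization and without 2 libraries. Genes higher in both subset comparisons numbered 2, and 1 with the replicate block and 106 without 2 libraries; lower genes numbered 1, and 2 with quantile normalization, 0 by limma with the replicate block and 27 without 2 libraries.

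The direction reversed for 3 results that were not called with 12 libraries, and the cause was not tested. CCR7 in naive activation was 1.03 without 2 libraries. PSAT1 at 48 h was -1.60 without 2 libraries, -1.33 with the same median added and -1.69 with the block added, and ran from -1.79 to 1.36 when libraries were left out. IMPDH2 at 48 h was -1.06 with library weights, -1.45 without 2 libraries, -1.18, -1.10 and -1.21 with the same median, quantile normalization and the block added, and ran from -1.45 to 1.05 when libraries were left out. Depth is known only relative to another library, so genes listed at 0 in the shallowest library carry no limit.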

Other observations

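The genes of this part were picked after their values were seen, and the fit without 2 libraries was chosen after seeing the data. In that fit IL2 and IL21, cytokine genes of early helper T cell responses, were listed at 0 in resting naive libraries and rose to 10.3 and 49.6 RPKM at 48 h (adjusted p = 4.39e-05 and 3.57e-06). IL7R, the receptor chain for the survival cytokine interleukin-7, fell from 93.6 to 16.5 in naive cells and from 170.2 to 11.9 in memory cells (adjusted p = 0.00037 and 6.42e-05).

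Granzyme genes moved apart in memory cells in the same fit: GZMK fell from 28.0 to 2.10 RPKM (adjusted p = 0.000781), while GZMB rose from 0.134 to 90.5 (adjusted p = 2.76e-05). SLC4A10, a marker of mucosal-associated invariant T cells, was at 1.81 and 8.75 RPKM in the 2 resting memory libraries, which lay far apart, and averaged 0.558 in resting naive libraries (adjusted p = 0.056), and ZBTB16, another marker of these cells, averaged 0.196 and 0.063.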
